A study of Bos taurus with 12 samples.

How the data were processed

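Whole blood DNA of 12 cows, 6 called subfertile and 6 called fertile in the labels, was converted enzymatically and sequenced, per the labels' protocols, from 1 mL of blood per cow. The submitters' processing notes name fastp 0.23.1, Bismark, DRAGEN and ChIPseeker 1.32.1 and the build ARS-UCD1.2. The statistical tool behind the deposited calls and the read minimum per site are not given in the sources used here. The deposited table gives, per cytosine, the percent methylated in each cow, the mean per group, the authors' difference in percentage points, a p-value and a q-value, per the file headers. All 216,990 sites had an absolute deposited difference above 25 percentage points (smallest 25.003, largest 93.8, median 34.7) and a q-value by the authors below 0.01 (largest 0.00999985). The authors' largest q over its p implies at least 16,455,735 tested sites in all. Deposited group means differed from the means of the cows' percent values by over 1e-6 at 0 sites. At 21,378 sites (9.85%) the unweighted difference was under 25 points, so the authors' deposited difference was not the unweighted one there, and how it was calculated is not given in the sources used here. All columns of per-cow values were matched to a cow by its number.

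The column prefixes F and R are carried by the cows that the labels place in the subfertile and fertile group. The meaning of the letters is not given, the labels were followed, and if the letters were meant the other way, every direction given here would turn. Only percent values are held, with no read counts, so the depth of each cow and the precision of each value are unknown and no read minimum could be set. The planned test was a logistic model on reads. It was replaced, as the design foresaw for percentages, by limma 3.58.1 in R 4.3.3 on log2 of (percent + 5)/(100 − percent + 5), with group as the only term and Benjamini-Hochberg adjustment over sites or genes. Sites passed at an adjusted p of at most 0.01 with a difference of at least 25 points, genes at 0.05. The 5 points added were chosen after the data were seen. Because the sites were selected by the authors on the same cows, all p-values describe the spread among these cows and are not independent evidence. No enrichment over the genome was computed, since sites that were not selected are not analysed here.

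Sites within 1 kb of each other formed 118,751 clusters, of which 70,872 held 1 site. Both strands of 47,992 CpG sites were present and gave 44.2% of the sites. A site was called genotype-like when at least 1 cow was under 10% and at least 1 over 80%, which held for 151,601 sites (69.9%). Autosomes held 213,833 sites, chromosome X 2,762 and unplaced scaffolds 395. Gene symbols came only from the deposited table, where 161,501 sites carry one. Intron and exon sites were assigned to the gene that holds them, because 26,981 of 79,351 (34.0%) lay inside another gene than the nearest. Promoter values per gene averaged at least 3 promoter sites per cow; gene values averaged all sites in promoter, exon, intron, untranslated and downstream regions and needed a value in all 12 cows.

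The 19 gene lists fixed before the data were examined were T cell, B cell, natural killer cell, monocyte, neutrophil, eosinophil and basophil, erythroid and platelet markers, cytokines and chemokines, pattern recognition, interferon response, antigen presentation, steroid and gonadotropin, endometrium and pregnancy, insulin and growth hormone, imprinted, DNA methylation machinery, glucocorticoid stress and age methylation genes. Since selection sets the group difference at every site, the direction of each list's genes was compared with other genes by Fisher's exact test, two-sided, as foreseen. Genes were named by a rule fixed before the data were examined: the 10 promoter sites with the largest positive and the 10 with the largest negative difference among passing sites with non-overlapping groups, 1 per gene; the 10 genes with the most passing sites; and up to 4 members per list with the largest difference. One gene that the rule takes for its number of sites is not reported here. "Passing" was read as the authors' deposited threshold after it was seen that no site passed limma. Groups were also compared by an exact two-sided permutation test over all splits of the cows for the mean level, and intervals for shares are exact binomial at 95%.

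The site test was checked on simulated data: 20,000 sites drawn from the residuals of the deposited sites, 50 of them shifted at each size. Limma called 0, 2, 8 and 38% of sites shifted by 25, 40, 60 and 80 points and none of the unshifted ones, of which 4.68% had an unadjusted p under 0.05. With only 200 sites shifted in all, adjustment is stricter than in the deposited table, so these shares do not carry over to it. The smallest acceptable share at 80 points was lowered after this result was seen. Alternatives covered the difference and q thresholds, genotype-like sites, autosomes, clusters, promoter distance, points added, plain percent values and leaving out each cow. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.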

Results

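Blood was taken from 12 dairy cows of 1 herd, kept on the same farm under the same conditions and aged 3 to 8 years. The 6 cows called subfertile left the herd within the following year because of reproductive complications that had not been recognised at sampling. The 6 cows called fertile stayed in the herd with no fertility problem. Each value analysed here is the percent of methylated calls at 1 cytosine in 1 cow, from sequencing after enzymatic conversion, in coordinates of the build ARS-UCD1.2. Methylated and hydroxymethylated cytosines are read alike by this chemistry. The deposited table held 216,990 cytosines, and all of them had already been selected by the authors for a difference between the groups. Values were given for all 12 cows at 176,455 sites (81.3%) and for at least 5 cows of each group at every site. The share of sites without a value ran from 0.669% in fertile cow 1 to 4.88% in subfertile cow 3. The number of reads behind a value is unknown. Levels are given as mean ± SD in percent methylated, subfertile cows first, with n = 6 per group unless another n is stated.

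The first comparison asked where in the genome the blood DNA of cows later culled for reproductive problems differed from that of cows that stayed. A compact difference lay around the type I interferon genes from IFNE to IFN-tau-c1 on chromosome 8, at promoter and distal intergenic sites. These genes include the interferon tau genes, whose product is the signal by which a ruminant embryo is recognised by its mother. No expression was measured here, so a link between this role and the difference in blood was not tested. From position 22,516,770 to 22,638,952, 87 deposited sites averaged 82.4 ± 1.40% in subfertile and 41.2 ± 1.05% in fertile cows, with groups as the labels name them. If the letters in the table's column names were meant the other way, every direction would turn. At 82 of these sites the subfertile mean was higher, and at 66 no fertile cow overlapped a subfertile cow. Only 14 of the 87 were promoter sites, and the others were distal intergenic. Sites nearest to IFNE, an interferon of the reproductive tract lining, averaged 80.9 ± 2.43% and 43.6 ± 1.89% over 30 sites. Sites nearest to IFNT3 averaged 82.0 ± 1.70% and 36 ± 2.22% over 27 sites, and those nearest to IFNT2 averaged 76.8 ± 3.59% and 41.4 ± 2.36% over 10 sites. Sites nearest to IFN-tau-c1 averaged 87.8 ± 3.69% and 44.5 ± 3.54% over 20 sites. The neighbouring LOC523244 and LOC100299481 had 82.3 ± 11.7% and 41.4 ± 2.67% over 21 sites, and 85.0 ± 5.12% and 39.0 ± 5.42% over 15 sites. On an unplaced scaffold, 12 sites nearest to IFNT had 93.79 ± 3.25% and 53.9 ± 3.95%. The interferon tau genes form a family of near-identical copies, so the placement of reads among copies is uncertain. The bounds of the region and its genes other than IFNT3 and LOC100299481 were chosen after their values were seen.

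**Figure D1:**
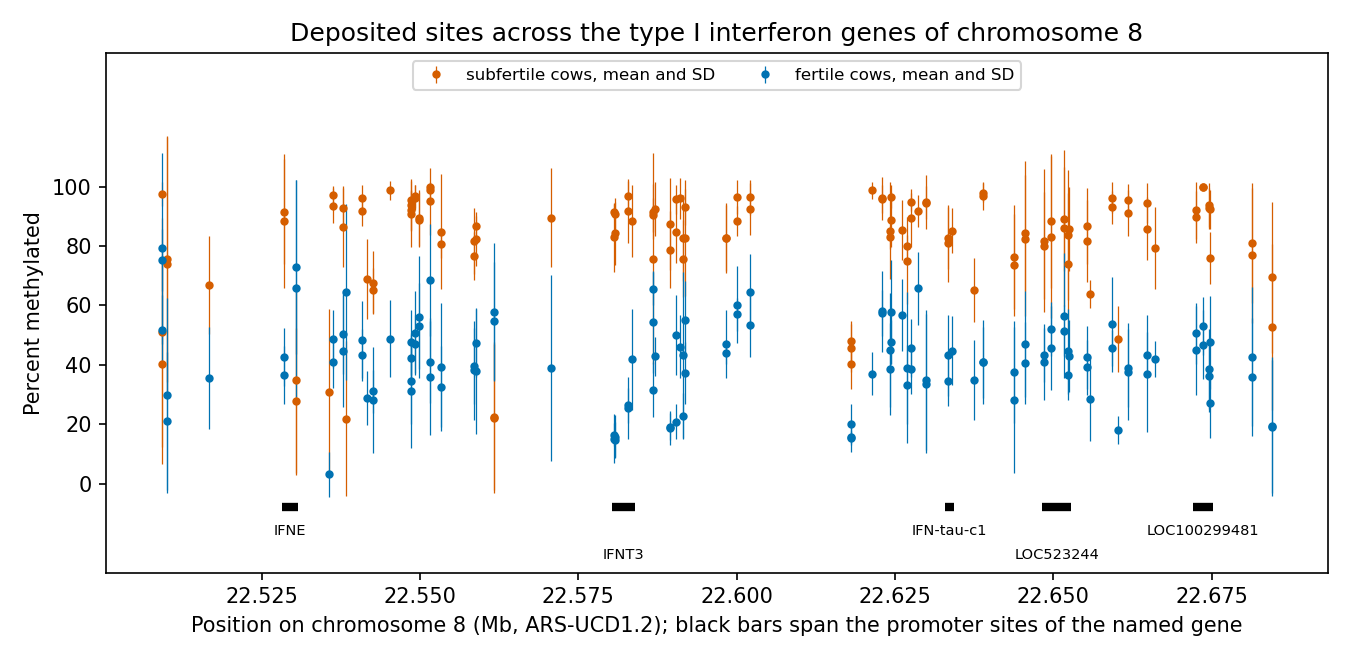
Percent methylated (vertical axis, mean and SD over the cows of a group) at the deposited sites across the type I interferon genes around IFNE and IFNT3, against position on chromosome 8 in Mb (horizontal axis), with black bars spanning the promoter sites of each named gene. From 22,516,770 to 22,638,952 the subfertile cows averaged 82.4% and the fertile cows 41.2%; SD bars can pass 0 and 100%.

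The difference was not confined to the interferon genes. Among the sites of chromosome 8, 717 of 12,162 (5.90%) separated the groups with no overlap of cows, against 2.93% of the sites on the other autosomes. Outside 14 to 26 Mb, bounds chosen after the values were seen, chromosome 8 had 206 of 9,053 (2.28%), so the excess lay in that stretch and not along the chromosome. Chance gives 0.216% for 6 cows against 6, although selection for a group difference raises this share at every deposited site. The window from 22 to 23 Mb held 122 such sites among 260 (46.9%), all of them higher in subfertile cows. Windows of the same chromosome from 18 to 19 Mb (27.1%) and from 24 to 25 Mb (27.0%), which hold no interferon site, were also among the 7 windows above 20%. Other interferon genes of chromosome 8 were nearest to 64 sites from 16 to 17 Mb, where 32 of 367 sites (8.72%) separated the groups. They were also nearest to 3 sites from 23 to 24 Mb, where 8 of 250 (3.2%) did. CDKN2A, a cyclin-dependent kinase inhibitor gene on chromosome 8, averaged 85.8 ± 4.88% and 45.1 ± 7.15% over 3 intragenic sites and was named after its values were seen.

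**Figure D2:**
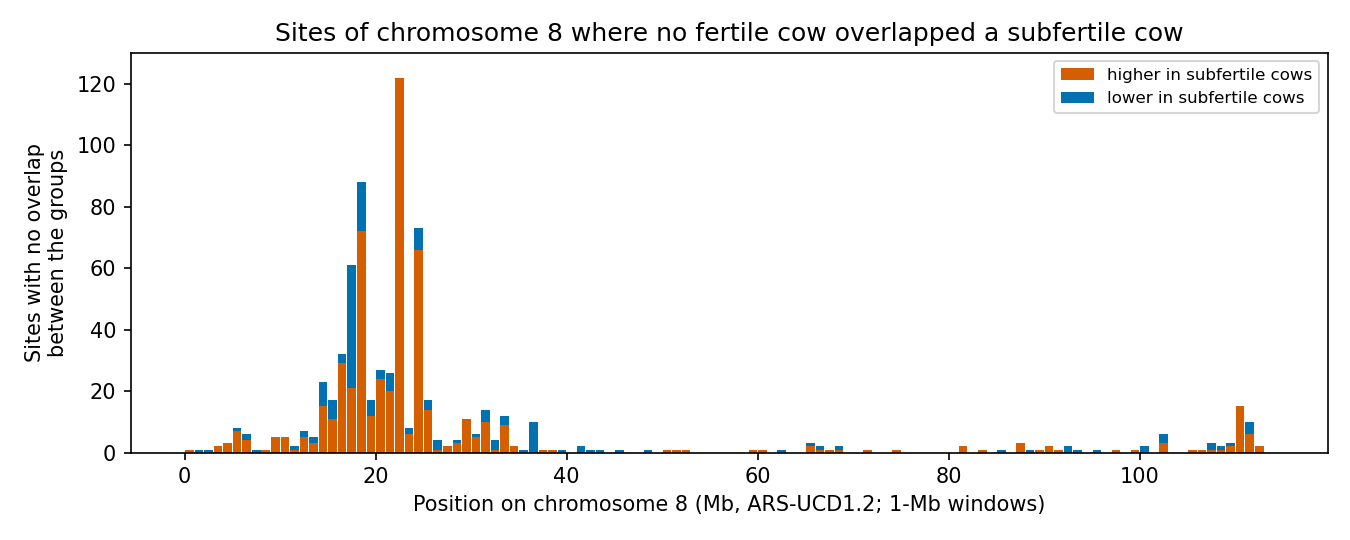
Deposited sites of chromosome 8 per window of 1 Mb (horizontal axis, position in Mb) where no fertile cow overlapped a subfertile cow (vertical axis, number of sites), split into sites higher and lower in subfertile cows. The window from 22 to 23 Mb reached 122 sites.

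Among promoter sites with non-overlapping groups, the largest differences of single sites were named. Higher in subfertile cows were sites in the promoters of IFNT3 (chromosome 8, position 22,580,721; 90.7 ± 5.55% against 14.7 ± 5.93%) and LOC112444666 (96.5 ± 5.92% against 28.8 ± 30.1%). ATG7, an autophagy gene, had 96.0 ± 5.61% against 33.3 ± 27.9%, and LOC512119 had 69.1 ± 23.8% against 9.75 ± 15.2%. DRC7, a gene of the ciliary dynein regulator, had 71.8 ± 21.8% against 7.77 ± 13.0%, and PC, which encodes pyruvate carboxylase, had 83.0 ± 23.8% (n = 5) against 21.2 ± 23.3%. KIFC3, DUSP8, SLC7A1 and LOC100299481 completed the 10 largest. Lower in subfertile cows were promoter sites of the coagulation factor gene F10 (4 ± 8.94% against 80.7 ± 21.9%, n = 5 in both groups) and of MAT1A, an enzyme of methionine metabolism (15.4 ± 24.9% against 87.7 ± 7.44%, n = 5 in both groups). SLC22A9 had 17.1 ± 13.9% against 85.7 ± 17.3%, TXLNA 13.2 ± 15.8% against 77.8 ± 19.8%, and IGHMBP2 27.5 ± 30.5% against 89.7 ± 11.6%. MIR129-1, SMIM19, ANGPTL8, MIR2285O-5 and HID1 completed the 10 largest in that direction. At all of these sites except those of SLC7A1 and LOC100299481, at least 1 cow lay under 10% and at least 1 over 80%, a pattern called genotype-like here. IFNT3 and LOC100299481 lie close together on chromosome 8, KIFC3 and DRC7 on chromosome 18, and LOC112444666 and SMIM19 on chromosome 27. Such pairs need not be separate results.

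Across cows, no single site passed when all sites were tested. Limma called 0 of 216,990 sites at an adjusted p of at most 0.01, with the smallest adjusted p at 0.0659, while 114,315 sites (52.7%) had an unadjusted p under 0.05. Without genotype-like sites 52 of 65,389 passed (47,714 at an adjusted p of at most 0.05), and 28 of 17,767 clusters of at least 3 averaged sites passed (4,338 at 0.05). Leaving out genotype-like sites removes sites by the spread of their cows, which itself favours small p-values. With plain percent values 0 sites passed (1,039 at 0.05). The median within-group SD was 27.3 percentage points. Simulated sites with this spread were called in 0% of cases at a shift of 25 points, 8% at 60 points and 38% at 80 points, with 200 of 20,000 sites shifted, so these rates do not carry over to a table selected for differences. The sites had been selected on the same cows, so the unadjusted share is not independent evidence.

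By direction, 113,097 deposited sites were higher and 103,893 lower in subfertile cows, 52.1% higher (95% exact binomial interval 51.9 to 52.3%, for counting error only). Counting sites within 1 kb once, 61,066 clusters were higher, 55,505 lower and 2,180 tied. Most sites, 124,455 (57.4%), were distal intergenic, and 53.2% of these were higher in subfertile cows. Introns held 76,977 sites (35.5%), promoters 12,017 (5.54%), exons 2,374, 3′ untranslated regions 935, downstream regions 212 and 5′ untranslated regions 20. Promoter clusters were higher in 51.7% and other clusters in 52.4% of cases, a difference that did not pass Fisher's exact test (two-sided p = 0.253). Among the 6,726 sites with non-overlapping groups (3.10%; chance 0.216%), 62.7% were higher in subfertile cows. In this subset, promoter clusters were higher in 55.4% and other clusters in 63.3% of cases (Fisher's exact p = 0.00354). The test counts clusters as independent, although deviations of cows were correlated between sites up to 2 Mb apart. Many of these sites also share 1 stretch of chromosome 8, so no lean of promoters is concluded.

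Promoter methylation per gene was compared to ask which genes differed over several promoter sites together. IFNT3 had 89.6 ± 4.53% against 22.2 ± 1.64% over 7 promoter sites (chromosome 8, 22,580,711 to 22,583,476; limma adjusted p 5.52e-05). LOC100299481 had 92.0 ± 2.63% against 43.3 ± 6.09% over 8 sites (limma adjusted p 0.000600), and IFN-tau-c1 82.9 ± 5.70% against 40.7 ± 8.29% over 3 sites (limma adjusted p 0.0139). Promoter levels also rose in SLC7A1, a cationic amino acid transporter (88.5 ± 17.5% against 42.7 ± 4.93%), PRKCD, a protein kinase C (97.5 ± 1.45% against 60.7 ± 19.6%), and AKT1, a kinase of insulin signalling (96.8 ± 3.24% against 56.2 ± 19.8%). IL21R, the receptor of interleukin-21, had 42.1 ± 22.7%, with every fertile cow and subfertile cow 5 listed at 0. Promoter levels fell in ZNF503, a zinc finger repressor (19.1 ± 5.21% against 55.4 ± 9.09%), TBX19, a regulator of pituitary corticotroph cells (51.2 ± 12.5% against 88.5 ± 7.41% over 13 sites), and SNED1, an extracellular matrix gene (12.1 ± 5.72% against 45.6 ± 15.2%).

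In all, 203 of 1,292 genes with at least 3 promoter sites passed limma at an adjusted p of at most 0.05, 97 higher and 106 lower in subfertile cows. A symbol was given for 158 of them, and in 39 no fertile cow overlapped a subfertile cow. At an unadjusted p under 0.05 the count was 671. INSIG1, a regulator of cholesterol synthesis, was higher over 38 sites (68.2 ± 17.7% against 29.2 ± 14.6%), LRATD2 lower over 16 sites (56.8 ± 20.3% against 90.2 ± 2.33%), and KIAA0825 lower over 16 sites (23.6 ± 37.6% against 84.7 ± 18.9%). Among the 16 members of the fixed gene lists tested here, 3 passed: AKT1, the granzyme gene GZMB (50.5 ± 21.1% against 88.2 ± 4.91%) and the macrophage scavenger receptor gene MSR1 (95.8 ± 2.73% against 63.7 ± 24.5%). Of the genes named to this point for their promoter means, only IFNT3, LOC100299481, SLC7A1, AKT1, GZMB and MSR1 were also taken by the fixed rule, and the others were named after their values were seen. The count fell to 4 without fertile cow 4 and to 19 with 1 instead of 5 percentage points added before the log ratio. At an unadjusted p under 0.05 limma gave 568 and 625 genes there, against 671, so the unadjusted counts fell far less than the adjusted ones. All 4 genes left without fertile cow 4 were higher in subfertile cows, so none of the lower genes passed there.

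**Figure D3:**
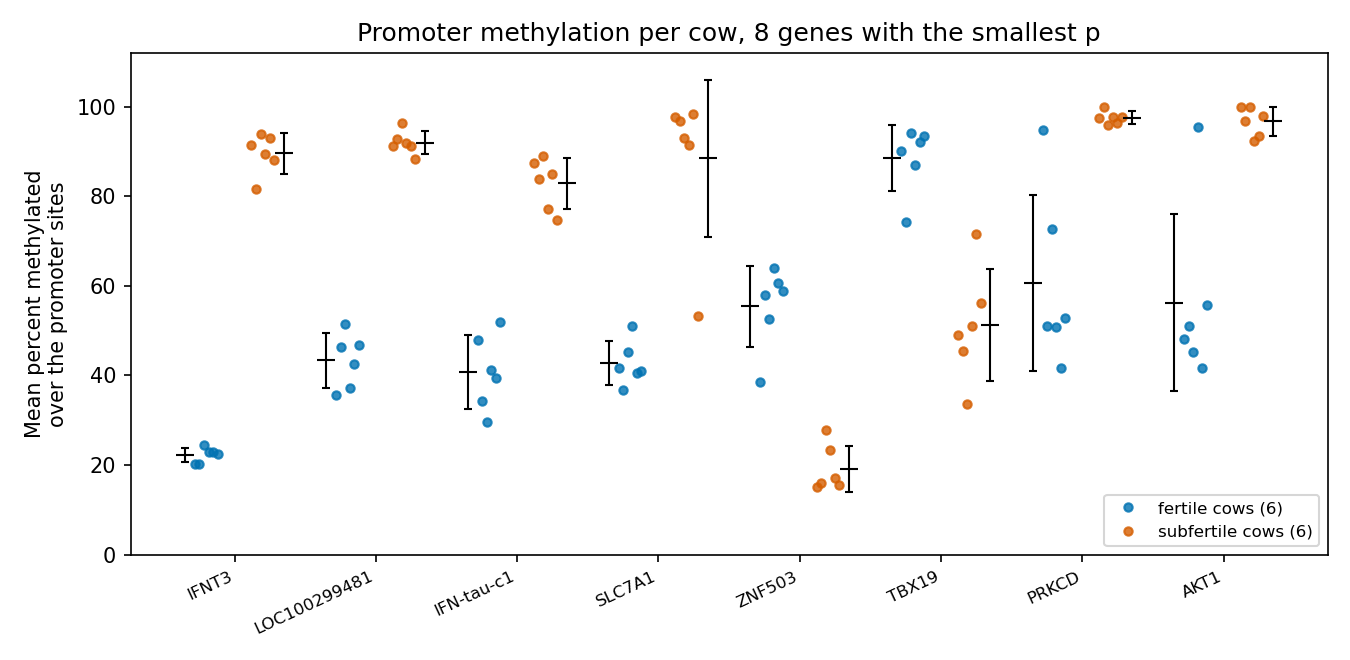
Mean percent methylated over the promoter sites of the 8 genes with the smallest p (vertical axis), 1 point per cow with the group mean and SD, for subfertile and fertile cows. The IFNT3 promoter averaged 89.6% in subfertile and 22.2% in fertile cows, and ZNF503 averaged 19.1% and 55.4%.

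Averaged over all sites in a gene's promoter, exons, introns, untranslated and downstream regions, 10 of 7,969 genes with a symbol passed limma at an adjusted p of at most 0.05. The adjustment also ran over genes without a symbol, which are not named here. Higher in subfertile cows were IFNT3, LOC100299481, LOC781948 (1 site), CDKN2A, IFN-tau-c1, ADI1 of the methionine salvage pathway (96.8 ± 3.95% against 64.6 ± 11%), GLUD1, which encodes glutamate dehydrogenase (97.4 ± 4.26% against 67.6 ± 11.6% at 1 site), and C1D (97.8 ± 3.6% against 59.2 ± 16.4% over 2 sites). Lower were LOC789841 (0 in every subfertile cow against 46.6 ± 16.6% at 1 site) and POLD4, a DNA polymerase subunit gene (2.38 ± 5.83% against 40.9 ± 12.6% at 1 site). The genes resting on 1 site passed at this looser threshold and over fewer tests, while no site passed among all sites. Of these 10 genes, all but IFNT3 and LOC100299481 were named after their values were seen. IFNT3, LOC100299481, LOC781948, CDKN2A and IFN-tau-c1 all lie in the window from 22 to 23 Mb of chromosome 8 described above. They are therefore not separate results. The genes with the most deposited sites differed in how many of their sites were higher or lower. FHIT held 401 sites, 174 higher and 227 lower, and FBXL17 held 339, 251 higher and 88 lower. MTUS2, which encodes a microtubule-associated protein, held 308 sites, 290 of them lower (26.2 ± 13.3% against 64.0 ± 9.97%; limma adjusted p 0.0553). MYO5B, a myosin gene, held 282 sites, 231 of them lower (33.2 ± 12.5% against 63.3 ± 11.1%; limma adjusted p 0.0645). SDK1 (273 sites), THSD7B (272), SLC39A11 (267), CDH23 (258) and EXOC4 (249) followed, and none of these genes passed in this fit. Over promoter sites alone, in the separate fit above, SDK1 (31.0 ± 20.6% against 74.2 ± 19.6% over 20 sites; limma adjusted p 0.0430) and MTUS2 (29.3 ± 20.9% against 67.6 ± 15.5% over 5 sites; limma adjusted p 0.0489) were lower in subfertile cows and passed.

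Gene lists fixed before the data were examined asked whether markers of blood cells, immune pathways, reproductive hormones and other themes differed together. Of 470 listed genes, 187 had a site in a gene feature and 173 could be tested. In limma's fit over all gene features, 0 list genes passed when adjusted over all genes and 66 had an unadjusted p under 0.05. Low unadjusted p-values are common among the selected sites: 671 of 1,292 genes lay under 0.05 in limma's separate promoter fit. The 66 are therefore not read as a result about the lists. In the separate fit of promoter means given above, AKT1, GZMB and MSR1 passed over all promoter genes. Adjusted over the list alone, 30 list members passed, 15 higher and 15 lower in subfertile cows. No list differed from the other genes in its share of higher genes by Fisher's exact test, with the smallest adjusted p at 0.757. Fisher's tests took every member with a site in the features used, and limma only members with a mean in all 12 cows, so their member counts can differ. Fisher's tests also count genes as independent, although members of the same or of different lists can lie close together. Examples are BOLA-DRA and BOLA-DRB3 on chromosome 23 and LTF and CCR2 on chromosome 22. List-alone results rest on sites already selected for this contrast, and members that only these results name were chosen after their values were seen.

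Of 9 tested natural killer cell genes, 1 was higher and 4 were lower, adjusted over the list alone, against 0 over all genes. GZMB (50.5 ± 21.1% against 88.2 ± 4.91%) and PRF1, which encodes perforin (17.7 ± 14.5% against 51.3 ± 22.3%), were lower, with KLRF1 (68.2 ± 27.3% against 95.9 ± 7.38%) and GZMM (68.7 ± 30.1% against 97.5 ± 2.90%). The higher member was NKG7 (78.0 ± 6.14% against 38.6 ± 21.5%), with the same values as at its 1 named site, which was genotype-like. The largest site differences of this list lay in NCR1 (93.9 ± 6.10%, n = 5, against 42.4 ± 47.2%), GZMB, NKG7 and KLRD1 (33.6 ± 30.6% against 71.8 ± 19.9%).

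Among 11 tested T cell genes, 0 were higher and 1 was lower, adjusted over the list alone, namely THEMIS (63.3 ± 23.9% against 93.4 ± 3.71%), against 0 over all genes. T cell sites with the largest differences lay in CD5 (45.8 ± 34.0% against 88.6 ± 21.6%), GATA3 (79.4 ± 32.6% against 40.3 ± 21.7%), BCL11B and ZAP70. Among 9 B cell genes, 1 was higher and 1 lower, adjusted over the list alone. These were BANK1, a B cell scaffold gene with 121 sites (77.0 ± 11% against 45.4 ± 13.1%), and MS4A1, which encodes CD20 (53.1 ± 29.8% against 88.7 ± 17.2%). Its largest site differences lay in BANK1 (97.0 ± 4.15%, n = 5, against 32.8 ± 27.1%), BLNK (65.7 ± 34.2% against 17.6 ± 27.3%), IRF4 and CD40.

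Of 5 monocyte genes, 1 was higher and 0 lower, adjusted over the list alone, namely MSR1 (87.9 ± 5.60% against 54.3 ± 21.2% over 12 sites). The chemokine receptor gene CCR2 had a site at 96.4 ± 8.75% against 51.1 ± 40.9%, and CD86 and CLEC4E completed the list's largest sites. Of 3 neutrophil genes, 1 was higher and 2 lower, adjusted over the list alone: LTF, which encodes lactoferrin (86.9 ± 1.40% against 51.5 ± 31.7% over 46 sites), MPO, which encodes myeloperoxidase (51.7 ± 27.1% against 87.3 ± 6.84%), and PADI4 (43.8 ± 17.2% against 73.1 ± 15.4%). The values given for MPO are those of its 1 named site. CXCR2 held the list's remaining named site. The named site of LTF lies close to that of CCR2 on chromosome 22, and in both fertile cow 2 was at 0 and fertile cows 4 and 5 at 100%. The LTF and CCR2 sites therefore need not be separate results. Eosinophil and basophil genes (3 tested), erythroid genes (1 tested) and platelet genes (4 tested) had 0 members passing, adjusted over the list alone. Their largest site differences lay in SIGLEC8 (39.3 ± 29.8% against 81.0 ± 25.1%), IL5RA and GATA2, in SLC4A1 (89.1 ± 19.7%, n = 5, against 49.9 ± 40.8%), and in ITGB3 (90.9 ± 9.55%, n = 5, against 29.0 ± 35.2%), SELP, VWF and ITGA2B.

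Of 14 cytokine and chemokine genes, 2 were higher and 1 lower, adjusted over the list alone: IL33 (74.5 ± 19.1% against 38.2 ± 6.74%), IL15 (77.5 ± 8.69% against 50.9 ± 6.80%) and IL1A (16.7 ± 25.8% against 72 ± 37.6%). The values given for IL1A are those of its 1 named site, which was genotype-like. The largest sites of this list also lay in TGFB2 (67.0 ± 16.9% against 27.6 ± 30.3%) and IL18 (13.1 ± 20.7% against 50 ± 28.5%). Of 14 pattern recognition genes, 1 was higher and 0 lower, adjusted over the list alone, namely LBP, which encodes the lipopolysaccharide binding protein (71.0 ± 5.13% against 42.6 ± 13.8%). NFKB1 (6.40 ± 11.2% against 61.2 ± 21.4%), NOD1, TLR9 and CGAS held its largest sites, and 7 of 9 members with promoter sites were lower (Fisher's exact p = 0.0967), against 8 of 14 over all gene features (p = 0.596). Of 12 interferon response genes, 1 was higher and 3 lower, adjusted over the list alone. IFIT2 (87.6 ± 7.15% against 49.5 ± 22.6%) was higher, and both interferon gamma receptor genes, IFNGR1 (29.8 ± 22.5% against 66.6 ± 13.4%) and IFNGR2 (53.9 ± 18.7% against 81.3 ± 10.1%), were lower with IFI44L. GBP4 had the list's largest site (62.4 ± 35.1% against 13.7 ± 21.3%), and MX2 was among its named sites. Of 8 antigen presentation genes, 1 was higher and 0 lower, adjusted over the list alone, namely the immunoproteasome gene PSMB9 (100% in every subfertile cow against 76.8 ± 20.1%). BOLA-NC1, BOLA-DRA (82.7 ± 19.2% against 38.2 ± 38.2%), NLRC5 and BOLA-DRB3 held its largest sites.

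Of 17 steroid and gonadotropin genes, 1 was higher and 0 lower, adjusted over the list alone, namely ESR1, the oestrogen receptor alpha gene (91.5 ± 4.70% against 66.3 ± 7.21% at 1 site). Intron sites differed most in GREB1, an oestrogen-responsive gene (18.0 ± 24.1% against 81.8 ± 21.8%), and in FSHR, the follicle-stimulating hormone receptor gene (73.7 ± 19.7% against 14.6 ± 20%, n = 5), followed by ESR2 and BMPR1B. Of 8 endometrium and pregnancy genes, 1 was higher and 3 lower, adjusted over the list alone. WNT7A (55.4 ± 15.5% against 76.7 ± 5.08% over 19 sites), IHH (29.8 ± 23.2% against 68.8 ± 26.7%) and GRP were lower, and LGALS3BP (73.9 ± 28.5% against 34.6 ± 21.4%) was higher. FKBP4 and FGF2 were also named by the rule, and 5 of 6 members with promoter sites were lower (Fisher's exact p = 0.111), against 7 of 10 over all gene features (p = 0.211).

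Of 18 insulin and growth hormone genes, 2 were higher and 0 lower, adjusted over the list alone: AKT1 (89.9 ± 5.90% against 57.2 ± 17.4% over 9 sites) and IGF1 (52.9 ± 32.4% against 7.02 ± 7.74% over 4 sites). At 1 genotype-like intron site of IGF1 every fertile cow and subfertile cows 1 and 5 were listed at 0, and the mean of 58.4 ± 48.2% in subfertile cows rests on the other 4. PPARGC1A and the imprinted growth factor gene IGF2 (21.0 ± 25.6% against 63.9 ± 37.1%) held the list's other named sites. Imprinted genes (4 tested), DNA methylation machinery (15 tested) and glucocorticoid stress genes (7 tested) had 0 members passing, adjusted over the list alone. Their largest sites lay in KCNQ1 (91.3 ± 14.6% against 33.7 ± 36.4%), GRB10 and PLAGL1, in HDAC4 (84.8 ± 21.4% against 38.6 ± 34.2%), TET3, DNMT3A and UHRF1, and in CRHR2 (66.0 ± 20.1% against 16.6 ± 20.3%), CRHR1, MC2R and POMC. Of 13 genes whose methylation is known to track age, 2 were higher and 0 lower, adjusted over the list alone: PDE4C (66.4 ± 13.9% against 32.7 ± 10.6%) and FHL2 (49.1 ± 19.3% against 16.5 ± 14.4%). LHFPL3 (78.9 ± 25.7% against 15.3 ± 22.6%, n = 5), CCDC102B, OTUD7A and ASPA held that list's largest sites, and all 4 members with promoter sites were higher (Fisher's exact p = 0.126), against 9 of 13 over all gene features (p = 0.272).

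Averaged per cow over the sites with 12 values, methylation was 54.8 ± 0.544% in subfertile and 53.4 ± 0.623% in fertile cows, a difference of 1.41 percentage points. The exact two-sided permutation p was 0.00216, the smallest that splits of 6 against 6 cows can give. This is the level of the selected sites and not of the genome. Every site had been selected for a difference on this same split, so the permutation p is not evidence of a shift in level. Cows of the same group correlated across these sites at a mean r of 0.425 (30 pairs, 0.370 to 0.498), and cows of different groups at 0.0740 (36 pairs, -0.0247 to 0.212). These are correlations across sites, which are not independent replicates. Selection of the sites for a group difference favours a higher r within than between groups, so the gap does not show that cows group by fertility. The first principal component held 32.2% of the variance and the second 8.32%, and the same selection favours a large first component.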

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

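All tests of explanations in this part except that of the cow numbers were chosen after the result was seen.

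At the 69.9% of sites called genotype-like, deviations of cows from their group mean followed those at nearby sites, with a mean squared correlation of 0.358 at 20 to 100 kb, against 0.1002 for sites on different chromosomes (0.283 against 0.1004 at the other sites). Noise from few reads is argued against by 0.523 at 5 to 20 kb, and a mix of blood cells that differs from cow to cow, as the whole cause, by the 0.1002 across chromosomes, the level of unrelated values. Methylation of a region moving one way is argued against at 20 to 100 kb, where the mean correlation was 0.273 of its root mean square, but it stays open up to 5 kb, where that share was at least 0.663. Sequence variants carried by the cows, or methylation that follows them, are consistent with the 0.358. Whether a variant removes the cytosine itself or a nearby variant goes with its methylation was not separated, and a difference related to fertility stays open and untested.

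Between 14 and 26 Mb of chromosome 8, bounds chosen after seeing the values, 511 of 3,109 sites (16.4%) separated the groups, 412 higher and 99 lower in subfertile cows, against 2.91% in the rest of the table. Reads shared between interferon gene copies as the whole cause are argued against by 27.1% of such sites from 18 to 19 Mb, where no interferon site lies, though within the interferon genes they stay open. Methylation raised along the whole stretch is argued against from 17 to 18 Mb, where only 34.4% of the 61 separating sites were higher. A chromosome segment shared by the cows of a group was not decided, since the frequency of separating sites on chromosome 8, at 2.02 times that on the other autosomes, rests on this stretch (2.28% outside it against 2.93%). This segment, shared ancestry, age and fertility itself are open, since parentage and genotypes are not analysed here.

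The groups separated along the first principal component, which selection of the sites favours, and the cow numbers in the labels begin with 3 or 4 in fertile and 6 or 7 in subfertile cows. If a trend with cow number were the whole cause, the higher-numbered cows within each group should lie nearer the subfertile end of the group difference than the lower-numbered ones, by a summed slope of 0.667. The summed slope was 0.0355, with an SD of 0.0599 over all choices of cows. Selection of the sites on this same split adds group difference that no trend would carry, so the low slope cannot exclude a trend. A step between numbers beginning with 3 or 4 and those beginning with 6 or 7 coincides with the groups and cannot be told apart from them. What the numbers stand for is not given in the labels, and age may still differ between the groups, since no age per cow is used here.

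In 30 of 264 groups of values (11.4%) the highest or lowest cow stood apart from the next by more than Dixon's 95% limit, where chance gives about 1 in 20 for normal values. Percents bounded at 0 and 100 with ties are not normal, so the 2 shares are not compared; the ratio of that gap to the group's range follows each value. Subfertile cow 3 lacked a value at 4.88% of sites, against 1.80% for the next cow (0.802). In promoter means, 1 subfertile cow had 53.3% in SLC7A1 against 91.6% for the next (0.848) and 1 had 58.1% in MEMO1 against 90.1% (0.763). Among fertile cows, 1 had 74.4% in TBX19 against 86.9% (0.637) and 1 had 95.5% in AKT1 against 55.8% (0.737). In gene means, a subfertile cow had 78.0% in CDH23 against 70.7% (0.675), a fertile cow 44.4% in GLUD1 against 69.2% (0.781), and a subfertile cow 14.3% in POLD4 where the others were at 0 (1).

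At single sites of subfertile cows, the lowest cow had 54.5% in SLC7A1 against 85.7% (0.686), 14.3% in GATA3 against 84.6% (0.821), 0% in BLNK against 63.6% (0.7), 78.6% in CCR2 against 100% (1) and 88.9% in CXCR2 against 100% (1). It had 54.5% in SLC4A1 against 90.9% (0.8), a lower level in SELP than the next cow at 83.3% (0.639), 45.5% in BOLA-DRA against 81.8% (0.667), 88.9% in AKT1 against 100% (1), 62.5% in KCNQ1 against 91.7% (0.778) and 50% in CRHR1 against 90.9% (0.818). The highest subfertile cow had 20% in F10 against 0 (1), 90% in KLRD1 against 33.3% (0.630), 57.1% in CD86 against 0 (1) and 100% in TGFB2 against 66.7% (0.722). At sites of fertile cows, the lowest cow had 92.3% in SMIM19 against 100% (1), 46.2% in CD5 against 85.7% (0.735), 66.7% in GZMB against 88.2% (0.647), 44.4% in WNT7A against 90% (0.820) and 0% in GRB10 against 70% (0.7). The highest fertile cow had 83.3% in GATA3 against 40% (0.743) and 100% in AKT1 against 46.7% (0.8).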

How the results depend on the processing

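Chosen after seeing the data were the points added, plain percent values, averaged clusters and strands, adjustment over the implied number of sites, promoters within 1 kb for genes, limma's unadjusted threshold, removal of genotype-like sites for the correlation between cows, and the reading of the counts over other splits. The global level and gene lists stayed on the same side of their thresholds, under the alternatives run for them. Leaving out 1 cow turned the sign at 1 to 39 deposited sites. The balance of higher and lower promoter genes turned in 7 of 18 alternatives (31 higher and 20 lower without fertile cow 2, 4 higher and 0 lower without fertile cow 4). That of list members turned in 12 of 304 pairs of list and alternative (natural killer cells 4 higher and 3 lower without fertile cow 6). Limma called 52 of 65,389 sites without genotype-like sites (47,714 at an adjusted p of at most 0.05 and 53,638 at an unadjusted p under 0.05), a filter that removes sites by the spread of their cows, and 28 of 17,767 clusters when at least 3 sites were averaged (4,338 at an adjusted p of at most 0.05), against 0 at 0.01 in the other alternatives (1,039 at 0.05 with plain percent values). As many sites as in the real grouping were called in 100 of 100 splits of the cows, the real one included (real 0, highest other 0), so this count cannot exclude chance. For promoter genes 1 of 100 splits gave as many, the real grouping itself (203, highest other 9), but since the sites had been selected on the real grouping, this comparison cannot exclude chance.

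Deposited sites numbered 104,323 at a difference of at least 35 points, 128,655 at a q of at most 0.001, 65,389 without genotype-like sites, 114,315 with limma's unadjusted p under 0.05 and 118,751 as clusters, and promoter sites 3,497 within 1 kb; these counts are smaller by construction. The share higher was 51.2%, 51.4%, 54.7% and 52.4% at 35 points, at a q of 0.001, without genotype-like sites and for clusters, and 51.3 to 52.8% leaving out each cow. Promoter clusters were higher in 52.9% and others in 55.2% without genotype-like sites (Fisher's exact p = 0.0195, over alternatives 0.0195 to 0.566, and 0.00354 among sites with non-overlapping groups, all counting clusters as independent); the cause was not tested. Promoter genes passing numbered 235 of 314 without genotype-like sites (99 of them among the 203), where the filter itself removes sites by the spread of their cows. Such genes numbered 98 within 1 kb, where fewer genes were tested, 19 with 1 point added and 319 with plain percent values, and the cause was not tested. They ranged from 4 to 182 leaving out 1 cow: 74, 51, 4, 129 and 98 without fertile cows 1, 2, 4, 5 and 6, and 35, 99, 31, 117 and 31 without subfertile cows 1, 2, 3, 4 and 6. The genes with an unadjusted limma p under 0.05 ranged only from 546 to 610 leaving out 1 cow. For the spread between animals, the mean correlation within a group was 0.635 without genotype-like sites, against 0.425 with them. The filter removes sites by the spread of their cows, which itself favours a higher correlation, so the rise is not a separate result.

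Not run, for want of read counts, were a minimum of 10 reads, removal of sites with extreme coverage, a binomial model without overdispersion, limma against the logistic model, and pooling by reads. Depth is unknown, so a value of 0 or 100% in a cow sets no bound. No paired analysis was possible because the numbers only name the cows.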

Other observations

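The regions in this part were chosen after their values were seen. On chromosome 25, 24 sites from 1,423,293 to 1,452,558, nearest to MEIOB, a gene of meiotic recombination, averaged 48.4 ± 3.63% (SD, n = 6) in subfertile and 3.46 ± 0.957% (n = 6) in fertile cows, all of them higher and 22 with no overlap of cows. Around LOC512119 on chromosome 17, 294 of 336 sites were higher in subfertile cows (58.9 ± 13.0% against 24.2 ± 7.89%, n = 6 each), and 273 of the sites were genotype-like. Within PDZRN3 on chromosome 22, 116 of 174 sites were higher (61.5 ± 5.01% against 48.1 ± 6.40%, n = 6 each), and 42 separated the groups. SLC24A2 on chromosome 8 had 79 higher and 55 lower sites, of which 59 separated the groups (57.7 ± 8.35% against 47.5 ± 5.45%, n = 6 each).

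From 11 to 12 Mb of chromosome 2, 72 of 237 sites separated the groups (30.4%), and all of these were higher in subfertile cows, with medians of 48.2% in subfertile and 0 in fertile cows. From 42 to 43 Mb of chromosome 29, 44 of 203 sites did so, and 29.5% of them were higher.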
